A study of Mus musculus with 6 samples.

How the data were processed

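Total RNA from 6 samples of mouse cardiac mesenchymal cells was sequenced, 3 from sham-operated hearts and 3 from hearts 28 days after 60 min of coronary occlusion and reperfusion. Per the labels' protocols, ribosomal RNA was removed, a directional library was made and both ends of each fragment were read. The submitters' processing notes name Trimmomatic 0.36, HISAT2, SAMtools, Cufflinks, StringTie and Cuffdiff and the mouse build GRCm38, without saying which step each performed. The version of the gene annotation was not given in the sources used here.

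The authors deposited FPKM values (fragments scaled to transcript length and library total) for 53460 genes, with 1 column per library, and beside them their own group FPKM values, standard deviations, a test score and p-values and q-values, per the file headers. These columns have the form of Cuffdiff's gene test, per the file headers. The mean of the 3 library columns differed from the authors' group FPKM by a median of -2.47% in the sham libraries and -2.46% in the infarct libraries. The authors' log2 fold column was not used here. The sham columns carry the numbers of the sham samples. The infarct columns are numbered differently from the infarct samples, so each was assigned to its group only, and the infarct library numbers used here are those of the table's columns.

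The table holds no counts, but its lowest values lie on steps. The ratios of these steps between libraries gave relative depths from 0.867 to 1.20, with a largest residual of 0.00142 on the log2 scale over pairs of libraries. In genes with 1 annotated transcript of 2 to 12 kb, the steps implied 20.3 to 28.2 M fragments per library. With that scale, 71.6% to 77.9% of the low values lay within 0.1 of a whole number of fragments, where evenly spread values would give 20%. The share includes the values at 1 fragment that set the scale, so 20% is not its chance rate. At this depth 1 FPKM on a 2 kb transcript stands for 40.6 to 56.5 fragments. These are estimates from the values, and they cover counting error only.

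Of the deposited genes, 28114 were at 0 in every library. The authors' status was OK for 14922 genes, not tested for 38519, failed for 5 and too many fragments to estimate for 14. Those 14 genes, which include the abundant Fn1, Malat1 and Ahnak, are listed at 0 in all libraries and were left out, since such a 0 is no measurement. Gene identifiers were matched to GENCODE M21, an annotation of GRCm38, which held 99.6% of them. The locus in the table was the same as the annotated gene in 60.3% of entries and covered it in 96.8%, because the table gives the merged locus of overlapping genes. Overlapping genes and near-identical copies are therefore uncertain. Entries of 1 symbol were summed, which concerned 110 symbols.

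Group differences were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with an intensity trend, over genes at 1 FPKM or more in at least 3 of the 6 libraries. The tests were two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05. Changes are given on the log2(FPKM + 1) scale, infarct minus sham, which understates the change of genes with low values. Folds are ratios of group mean FPKM. Of 45 gene lists (cell types, matrix, signalling, stress, metabolism, cell cycle), the 40 with at least 5 tested members were compared with all other genes by camera from limma with a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance, were alternatives. Members were also counted after adjustment over the list alone. The deposited calls of the authors were compared with the lists by a two-sided Fisher's exact test against the 14922 genes with status OK, adjusted over 86 tests. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.

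Lists, tests, alternatives and the rule for named genes were fixed before the data were examined, except where stated. The rule named the 10 largest changes in each direction among genes past the threshold with separated groups and a mean of at least 1 FPKM in the higher group. Where fewer than 5 passed in a direction, it named the 10 with the smallest unadjusted p. From each list it named up to 4 members with the smallest p, and from lists of cell identity also the 3 most abundant. The sex-linked genes were named to check the labels. Gene models without a name were counted, not named, apart from those singled out below.

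The test was checked on 20 simulated data sets of 12720 genes with the means of the real ones and 200 changed genes. Noise was normal, with the spread of each gene as limma estimates it after borrowing from genes of like level. For the comparison of infarct with sham libraries it recovered 12.0% of genes changed by 0.5 on the log2 scale, 77.3% of those changed by 1, 98.1% of those changed by 2 and 100% of those changed by 4. Of its calls, 6.25% were unchanged genes. A list of 25 genes lowered by 1 was called in 20 of 20 runs, and 0.15 unchanged lists were called per run. The simulated genes varied independently of each other, which real genes do not. Real genes with wide spreads can be missed even at a change of 4. Emcn at -4.59 and Cdh5 at -4.21 were not called over all genes (limma, adjusted p = 0.380 each).

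Alternatives covered median scaling, quantile normalization, pseudocounts of 0.1 and 0.01, no filter and a filter at 5 FPKM, limma without the trend, with robust estimation and with library weights, each library left out, other thresholds, the highest entry per symbol, and small, ribosomal and mitochondrial RNA left out. After the data were seen, fits without genes whose longest transcript is under 300 nt, fits on protein-coding genes only and lists without endothelial members were added. Levels of the endothelial list per library are geometric means over all 23 tested members with pseudocounts of 1 and 0.01 FPKM. For the test of scaling, its level-matched genes were those within 100 ranks of a member in mean level. A fit with the replicate number as a block could not be made.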

Results

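Cardiac mesenchymal cells are stromal cells grown from the heart. Here the slowly adherent fraction was used. RNA was measured in cells from mouse hearts taken 28 days after surgery. There were 3 libraries from sham-operated hearts and 3 from hearts that had undergone 60 min of coronary occlusion followed by reperfusion, called infarct libraries here. The comparison asks how the RNA of these cells differs with the state of the heart they came from. The labels do not say whether the libraries of a group came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical. Each library held 12545 to 12703 genes at 1 FPKM or more, at an implied depth of 20.3 to 28.2 M fragments. The 10 most abundant genes took 39.0% to 49.2% of the FPKM sum, and 8 of them do not code for protein.

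Genes of stromal cells were abundant in both groups. The collagen gene Col1a1 stood at 732 ± 120 FPKM in sham and 899 ± 146 in infarct libraries (SD, n = 3 each, as for all values below). The matrix Gla protein gene Mgp stood at 2749 ± 1242 and 2406 ± 1418. The integrin gene Itgb1 stood at 455 ± 30.8 and 448 ± 61.5, and the smooth muscle actin gene Acta2 at 396 ± 73.9 and 455 ± 105. The cardiac transcription factor genes Tbx20 and Gata4 were measured at 157 ± 86.8 and 35.8 ± 10.3 in sham and 145 ± 53.5 and 38.8 ± 7.85 in infarct libraries. None of these 6 genes passed the test. Some markers of other cell types were measured as well. Of the 28 cardiomyocyte markers 7 reached the filter, among them Atp2a2, the gene of a calcium pump, at 68.4 ± 2.29 and 72.4 ± 4.37 FPKM and Tnnt2, the gene of cardiac troponin T, at 30.4 ± 19.9 and 16.6 ± 3.32. Among macrophage markers, the lysozyme gene Lyz2 was at 18.7 ± 10.4 and 21.5 ± 10.2 FPKM and the galectin 3 gene Lgals3 at 17.5 ± 4.04 and 15.1 ± 1.94, while the leukocyte gene Ptprc did not exceed 0.0528 FPKM in any library. Of the macrophage list only 4 genes reached the filter, of the lymphocyte and mast cell list 1, of the skeletal muscle list 3 and of the erythroid and platelet list 2, so these lists were not tested.

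Endothelial genes were lower in the infarct libraries. Of the 23 tested members of the endothelial list, all 23 had a negative change, with a median of -1.65. Adjusted over the list alone, 17 fell, and the same 17 had separated groups. Chance separates 10% of single genes, but the members varied together within groups. The 17 are therefore not separate tests, and their share cannot be set against that rate. Adjusted over all 12720 genes, 1 fell, Mmrn2, a gene of the endothelial extracellular matrix. Pecam1 (chromosome 11, 106654217 to 106750628), which encodes an adhesion molecule of endothelial junctions, fell from 33.8 ± 22.9 to 1.06 ± 1.28 FPKM, a log2 change of -3.97 with an SE of 0.647 and an adjusted p of 0.00218 over the list alone. Cdh5, the gene of the endothelial cadherin, fell from 46.9 ± 27.2 to 1.77 ± 2.26 FPKM and Emcn, the gene of an endothelial sialomucin, from 82.0 ± 53.4 to 2.93 ± 3.85. Over all 23 members, sham means were 1.22 to 31.8 times the infarct means, with a median of 12.2. Infarct library 1 held the highest infarct values of Pecam1, Cdh5 and Emcn. Without it the range was 1.10 to 172 with a median of 19.9. The 172 was for Tie1, at 0 and 0.103 FPKM in infarct libraries 2 and 3, so it rests on very low values. Without infarct library 2 the median was 8.16, and without sham library 1 the lowest ratio was 0.602, for Ly6c1. Eng, the most abundant member, was at 109.7 ± 17.5 and 89.7 ± 17.2 FPKM and did not pass.

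The list lay below other genes by camera with an adjusted p of 3.53e-38 at the preset correlation. It did not pass with an estimated correlation (adjusted p = 0.315 with an estimated correlation) or with fry (adjusted p = 0.160). The mean pairwise correlation of its members within groups was 0.356, far above the preset 0.01. The p-value at the preset correlation therefore overstates the evidence. With a pseudocount of 1 FPKM, the geometric mean level of all 23 members relative to the sham mean was 66.2%, 139% and 109% in sham libraries 1 to 3 and 33.9%, 22.4% and 25.7% in infarct libraries 1 to 3. With a pseudocount of 0.01 FPKM the infarct levels were 24.0%, 6.13% and 12.0%. With a filter of 5 FPKM, which tests fewer members, 9 fell after adjustment over the list alone.

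**Figure D1:**
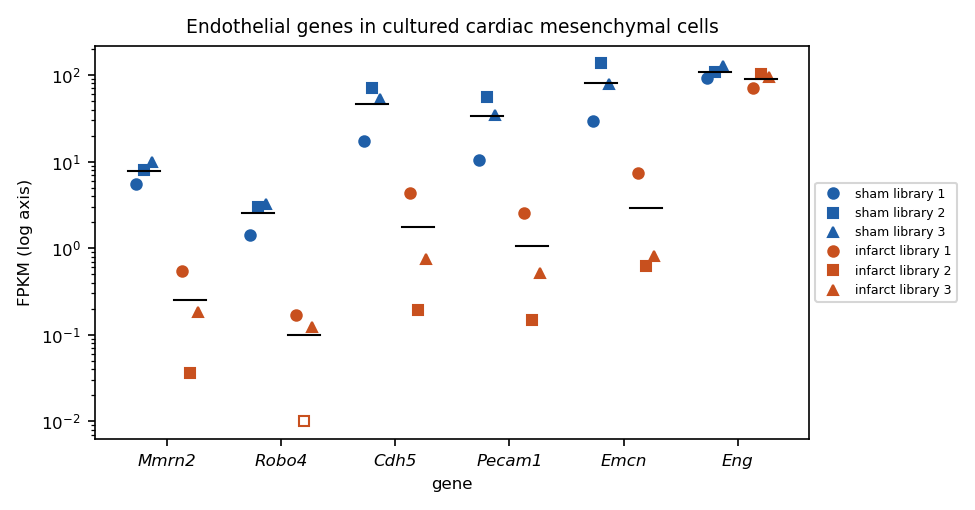
Values of 6 endothelial genes in FPKM on a log axis, 1 point per library, sham in blue and infarct in orange, with a bar at the group mean of 3 libraries. The open square marks Robo4 in infarct library 2, listed at 0 and drawn at 0.01. For Mmrn2, Robo4, Cdh5, Pecam1 and Emcn every sham library lies above every infarct library, and for Eng the groups overlap.

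Over all 12720 genes, limma called 3 genes, 1 lower and 2 higher in infarct libraries. Unadjusted p was under 0.05 for 456 genes, 292 lower and 164 higher. This is a smaller share of the 12720 genes than the 0.05 that chance gives. The groups were separated for 994 genes, 7.81% of those tested, where chance gives 10%. Mmrn2 (chromosome 14, 34375465 to 34404287) fell from 7.73 ± 2.16 to 0.254 ± 0.261 FPKM, with a log2 change of -2.79, an SE of 0.235 and an adjusted p of 0.0329. Its call ended when genes with transcripts under 300 nt were left out (adjusted p = 0.0846, over a range of 0.0166 to 0.429 across alternatives), which removes both genes called higher, and with pseudocounts of 0.1 (0.267) and 0.01 (0.429) or no filter (0.185). It also ended without sham library 2 (0.221), sham library 3 (0.138) and infarct libraries 1 (0.118), 2 (0.226) or 3 (0.245).

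Both genes called higher were short gene models without a name, singled out after their values were seen. Gm10060, a processed pseudogene with a transcript of 111 nt (chromosome 8, 19784746 to 19784856), was listed at 0 in the 3 sham libraries and at 16491, 83531 and 17903 FPKM in infarct libraries 1 to 3. Gm27390 is a non-coding RNA with a transcript of 176 nt (chromosome 1, 63177983 to 63178158). It was listed at 0 in the sham libraries and at 12.3, 16.6 and 6.66 FPKM in infarct libraries 1 to 3. Its listed locus, 62958418 to 63180486, is a merged locus of overlapping genes, so its reads are uncertain. The authors' deposited table calls Gm10060 (q = 0.0266) but not Gm27390 (q = 0.793). With limma the adjusted p was 0.000606 for Gm10060 and 0.0329 for Gm27390. Gm27390 was not called without sham library 2 (adjusted p = 0.191), sham library 3 (0.138), infarct library 1 (0.243) or infarct library 2 (0.0905), or without a filter (0.185), over a range of 0.00327 to 0.243 across alternatives. Gm21769, which differs from Gm10060 at 1 position, was listed at 33097 FPKM in sham library 1 and at 0 in the other 5 libraries, so reads of these copies are uncertain.

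The genes next in rank among those lower in infarct libraries did not pass over all genes. They included Bcl6b, a transcriptional repressor gene, at 5.70 ± 2.09 and 0.267 ± 0.256 FPKM, and Cd93, a C-type lectin-like receptor gene expressed by endothelial cells, at 11.4 ± 5.56 and 0.575 ± 0.446. Selp, the gene of P-selectin, was at 29.5 ± 11.4 and 6.37 ± 0.943, and Robo4, an endothelial guidance receptor gene, at 2.54 ± 0.976 and 0.0984 ± 0.0884. Tspan18 was at 3.53 ± 0.561 and 0.720 ± 0.302 FPKM, Fam167b at 3.60 ± 1.28 and 0.163 ± 0.232 and Gimap6 at 5.33 ± 2.39 and 0.553 ± 0.0467. Their adjusted p ranged from 0.197 for Bcl6b to 0.279 for Gimap6. Zeb1, whose locus overlaps other genes, was at 244, 269 and 946 FPKM in sham libraries 1 to 3 and at 45.2, 32.0 and 42.8 in infarct libraries 1 to 3 (adjusted p = 0.301). Without sham library 1, where endothelial genes were lowest among sham libraries, 14 genes were called, 12 of them lower, among them Bcl6b, Selp, Fam167b, Cd93, Robo4 and Gimap6. Without sham library 3, Zeb1 passed with an adjusted p of 0.0255.

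Among genes with a name, limma called 0 higher, against 164 genes of any kind at an unadjusted p under 0.05. The first in rank was Gpx3, the gene of a secreted glutathione peroxidase, at 26.7 ± 3.402 FPKM in sham and 64.8 ± 21.01 in infarct libraries, a log2 change of 1.21 with an SE of 0.219 and an adjusted p of 0.427 over all genes. Spon2, an extracellular matrix gene, was at 7.75 ± 2.03 and 20.7 ± 8.54, and S1pr3, a receptor gene for sphingosine 1-phosphate, at 3.87 ± 0.702 and 9.996 ± 4.04. Adamts14, a procollagen protease gene, was at 2.59 ± 0.439 and 4.73 ± 0.939. Lst1, Ttyh2, Rhox5, Dleu2, Ak5 and Lmo7 completed the 10, with folds from 1.42 for Ttyh2 and Ak5 to 4.03 for Lst1. All 10 had separated groups, and the highest adjusted p among them was 0.703 for Spon2 and Lmo7.

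Secreted factor genes were tested as a list of 36, of which 3 fell after adjustment over the list alone and none after adjustment over all genes. These were Pgf, the gene of placental growth factor, at 3.05 ± 0.900 and 0.763 ± 0.0610 FPKM, Edn1, the gene of endothelin 1, at 24.2 ± 11.8 and 5.87 ± 0.496, and Angpt2, the gene of angiopoietin 2, at 7.61 ± 1.28 and 2.64 ± 1.55. Apln, the gene of apelin, was at 13.4 ± 4.65 and 5.91 ± 1.37 and did not pass. The list as a whole did not pass (adjusted p = 0.314), and its median of 0.02 and mean of -0.09 differ in sign. In the Notch list, 1 of 13 genes fell when adjusted over the list alone, Nrarp, at 6.47 ± 4.62 and 0.534 ± 0.303 FPKM. Endothelial markers were lower in the same 3 libraries. In the NF-kB list of 20 genes the adhesion gene Icam1 was at 24.2 ± 13.04 and 7.78 ± 1.09 FPKM, and no member passed.

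Besides the endothelial list, 9 lists passed camera at the preset correlation, with medians between -0.08 and 0.33. None passed with an estimated correlation, where their adjusted p ran from 0.707 to 0.927, and none with fry. In 7 of the 9 no member passed over the list alone. Cytokine and chemokine genes lay higher in infarct libraries (24 tested, median 0.33, adjusted p = 0.00444, and adjusted p = 0.707 with an estimated correlation). Its leading members did not pass singly. The chemokine gene Cxcl14 was at 2.34 ± 0.395 and 4.47 ± 1.15 FPKM, Lif, an interleukin 6 family gene, at 7.93 ± 1.81 and 12.7 ± 1.56 and the chemokine gene Ccl7 at 26.3 ± 6.56 and 51.1 ± 19.6. Without infarct library 2 the adjusted p of the list was 0.0979.

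NRF2 target and antioxidant genes lay higher (30 tested, 26 positive, median 0.14, adjusted p = 3.02e-04, and adjusted p = 0.710 with an estimated correlation). Of them, 1 rose when adjusted over the list alone, Gpx3, and none over all genes. Without sham library 2 the adjusted p of the list was 0.0536. Immediate early and heat shock genes lay lower (31 tested, 19 negative, median -0.08, adjusted p = 0.00283, and adjusted p = 0.707 with an estimated correlation). The transcription factor gene Atf3, at 3.04 ± 0.178 and 1.48 ± 0.211 FPKM, fell when adjusted over the list alone. Klf2, a flow-responsive factor gene, was at 24.3 ± 2.02 and 17.0 ± 2.04, and Jun at 25.9 ± 3.88 and 19.9 ± 1.63. The list did not pass without sham library 2 (adjusted p = 0.0674) or infarct library 3 (0.0798).

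Osteogenic and chondrogenic genes lay higher (11 tested, 9 positive, median 0.14, adjusted p = 0.0347, and adjusted p = 0.707 with an estimated correlation). Runx2, a master factor of bone formation, was at 9.68 ± 0.739 FPKM in sham and 1.45 times that in infarct libraries, and Col2a1, a cartilage collagen gene, at 4.54 ± 1.90 and 6.96 ± 0.197. The list did not pass without sham library 2 (0.227) or infarct library 3 (0.144), with no filter (0.338) or with a filter of 5 FPKM (0.0779). Genes of matrix crosslinking and proteolysis lay higher (37 tested, 27 positive, median 0.12, adjusted p = 0.0347, and adjusted p = 0.927 with an estimated correlation). The protease gene Adamts4 was at 3.06 ± 0.395 and 4.09 ± 0.379. That list did not pass without sham library 2 (0.678), infarct library 2 (0.295) or infarct library 3 (0.658), or with a filter of 5 FPKM (0.0779).

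Nuclear genes of oxidative phosphorylation (58 tested, 46 positive, median 0.06, adjusted p = 0.0297) and glycolysis genes (24 tested, 19 positive, median 0.06, adjusted p = 0.0434) lay slightly higher, each with adjusted p = 0.927 with an estimated correlation. Hk2, the gene of hexokinase 2, was at 7.25 ± 2.11 and 10.6 ± 0.828 FPKM. The first list did not pass without sham library 3 (0.164) or infarct library 1 (0.454), and the second without sham library 2 (0.0642), sham library 3 (0.529) or infarct library 2 (0.761). Neither passed with quantile normalization (0.0843 for each), without the trend (0.0509 and 0.0522) or without small, ribosomal and mitochondrial RNA (0.828 and 0.119). Mesenchymal surface marker genes lay lower (22 tested, 13 negative, median -0.03, adjusted p = 0.0434, and adjusted p = 0.713 with an estimated correlation). Thy1 was at 289.8 ± 16.3 and 225 ± 35.3 and Nes at 61.6 ± 15.2 and 44.5 ± 3.20. Without the members it shares with the endothelial list, its adjusted p was 0.0666. It also did not pass without sham library 1 (0.560) or infarct library 1 (0.309), with median scaling (0.0578), no filter (0.113) or a filter of 5 FPKM (0.116), without the trend (0.0522), or without small, ribosomal and mitochondrial RNA (0.0788).

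Genes of S phase lay higher (40 tested, 36 positive, median 0.14, adjusted p = 0.0434, and adjusted p = 0.927 with an estimated correlation), but this rested on single libraries. The list turned lower without infarct library 1 (adjusted p = 0.116) and without sham library 3 (0.871), and did not pass without sham library 1 (0.583), with no filter (0.0538) or a filter of 5 FPKM (0.121), or without the trend (0.0522). The topoisomerase gene Top2a was at 82.7 FPKM in infarct library 1 and 55.7 in sham library 2, and at 23.01 to 37.4 in the other 4 libraries. The first principal component, 40.0% of the variance, placed these same libraries together, and the second, 28.6%, separated the groups. Correlations across genes ran from 0.955 to 0.983 between groups, 0.966 to 0.987 within the infarct group and 0.967 to 0.982 within the sham group.

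The other 30 tested lists did not pass, with adjusted p from 0.0651 for G2 and M phase genes to 0.879 for TGF-beta signalling and targets, and medians from -0.08 to 0.22. In 27 of them no member passed over the list alone, and in 6 the median and mean differed in sign. Atf3 was the 1 gene of the ER stress and ATF4 list that fell over the list alone. Fibrillar collagens and structural matrix genes had a median of 0.09 (33 tested, adjusted p = 0.270), cardiac fibroblast markers 0.08 (18 tested, adjusted p = 0.426) and myofibroblast and contractile genes 0.07 (28 tested, adjusted p = 0.0659). Among the latter, the smooth muscle actin gene Actg2 was at 2.49 ± 1.17 and 7.91 ± 4.52 FPKM and did not pass. Interferon response genes had a median of -0.03 (40 tested, adjusted p = 0.777) and hypoxia targets 0.12 (27 tested, adjusted p = 0.242). Pericyte and smooth muscle markers had a median of 0.07 (16 tested, adjusted p = 0.798) and cardiomyocyte markers -0.08 (7 tested, adjusted p = 0.426).

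**Figure D2:**
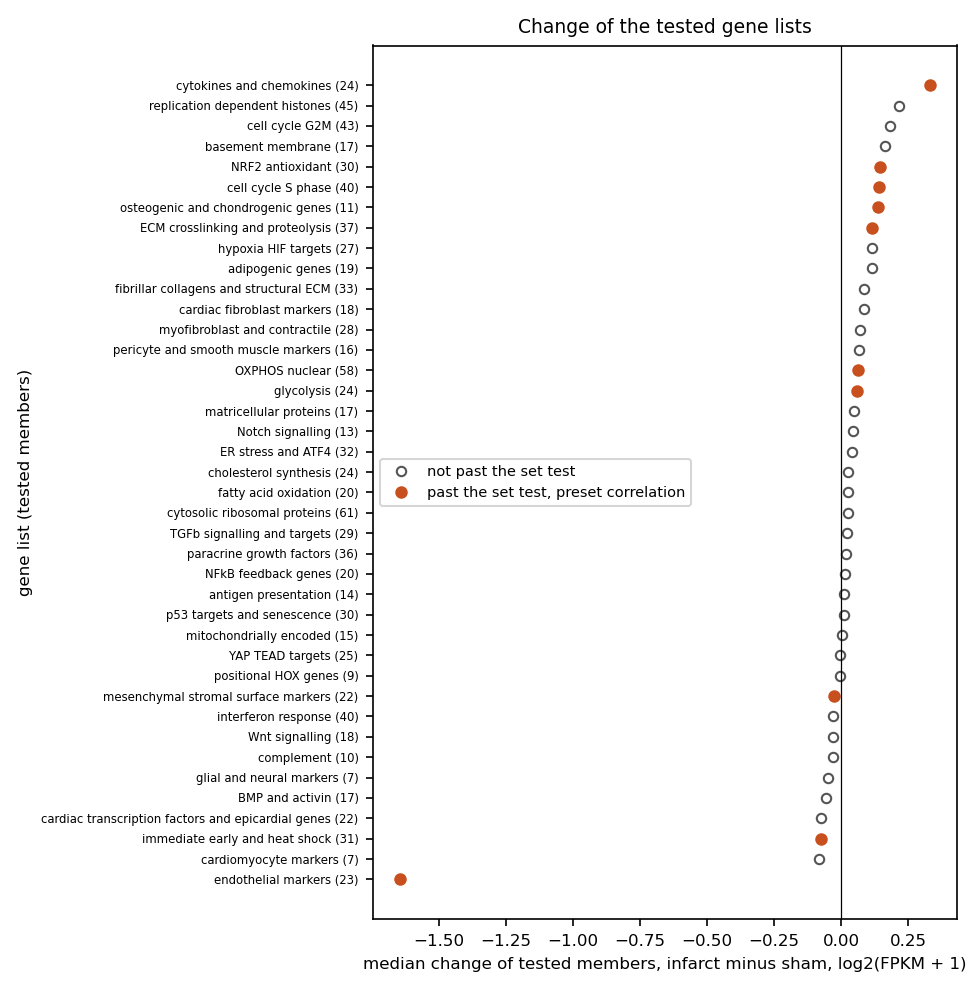
Median change of the tested members of each of 40 gene lists, infarct minus sham, on the log2(FPKM + 1) scale, with the number of tested members in brackets. Filled points passed camera at the preset correlation, open points did not. The endothelial list lies at -1.65, and the other 39 lie between -0.08 and 0.33.

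The sex-linked genes did not match the labels, which call all animals male. Xist, the RNA that silences an X chromosome in female cells, was at 105 ± 4.88 FPKM in sham and 78.2 ± 13.7 in infarct libraries, with no library under 63.1. The Y-linked gene Ddx3y was at 0.0869 ± 0.0280 FPKM in sham and 2.72 ± 2.96 in infarct libraries, with 6.07, 0.451 and 1.65 in infarct libraries 1 to 3. The Y-linked genes Uty, Kdm5d and Eif2s3y followed the same order of libraries, with folds of 35.9, 37.7 and 27.1 between group means. Without infarct library 1 these folds were 14.6, 15.9 and 9.12, and that of Ddx3y was 12.1 in place of 31.3, while without sham library 1 that of Kdm5d was 61.1. All 4 had separated groups, for which an exact two-sided permutation test gives 0.1, the smallest p that 3 against 3 allows. These genes lay under the filter and were not part of the genes tested. Their difference runs with the groups, so a different mix of cells cannot be separated from the infarct in any comparison here. Xist, the 1 tested gene of the sex-linked list, had a log2 change of -0.44 with an SE of 0.139 and did not pass over all genes. The order of the infarct libraries in Y-linked genes, library 1 highest and library 2 lowest, was that of the endothelial list's geometric mean level, but not of each member, since Flt1 and Eng were lowest in infarct library 1.

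**Figure D3:**
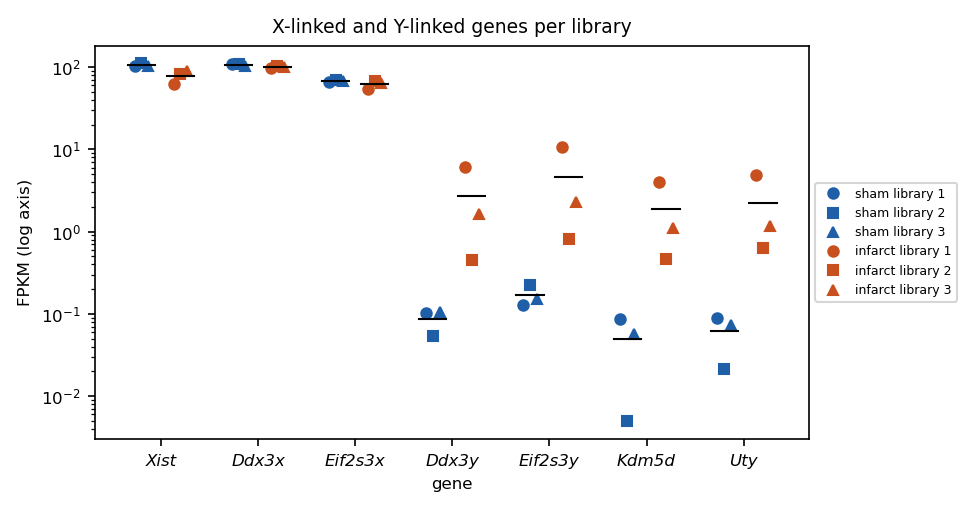
Values of Xist, 2 X-linked genes and 4 Y-linked genes in FPKM on a log axis, 1 point per library, sham in blue and infarct in orange, with a bar at the group mean of 3 libraries. Xist lies at 63.1 or above in all 6 libraries, and each Y-linked gene lies higher in the 3 infarct than in the 3 sham libraries.

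The authors' deposited table calls 247 genes, 177 lower and 70 higher in infarct libraries, at q-values up to 0.0495. In the authors' deposited table, endothelial list genes made up 17 of the lower calls where 0.321 were expected among 27 tested (Fisher's exact test, adjusted p = 5.55e-25). In the authors' deposited table, secreted factor genes made up 6 of the lower calls where 0.499 were expected (adjusted p = 2.04e-04) and 3 of the higher calls where 0.197 were expected (adjusted p = 0.0143). By the authors' deposited table, cytokine and chemokine genes made up 4 of the higher calls where 0.127 were expected (adjusted p = 2.04e-04), and myofibroblast genes 3 where 0.136 were expected (adjusted p = 0.00571). Cardiac fibroblast markers made up 3 of the lower calls of the authors' deposited table where 0.297 were expected, and Wnt genes 3 where 0.309 were expected (adjusted p = 0.0376 for each). Of 5 sex-linked genes, 4 were among the higher calls of the authors' deposited table (adjusted p = 9.56e-08). Fisher's exact test counts genes as independent, so its p-values overstate the evidence where members of a list vary together. The 4 Y-linked genes followed the same order of infarct libraries, and the endothelial members varied together within groups. The groups were separated for 132 of the 177 lower calls and for 31 of the 70 higher calls. Among all genes with status OK in the authors' deposited table the share was 8.84%, where chance gives 10%. The calls were made from these same libraries, so this excess is not separate evidence. Among calls of the authors' deposited table, infarct library 1 was the highest infarct library in 54 of the 70 higher ones and exceeded both others more than 2 times in 42. Sham library 2 was the highest sham library in 107 of the 177 lower calls of the authors' deposited table. Of the genes called in the authors' deposited table, 165 were also tested by limma, all 165 in the same direction and 104 at an unadjusted p under 0.05. Both tests used the same libraries, so the shared direction is no independent support.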

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

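All tests in this part were chosen after the results were seen.

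A signal of 4 Y-linked genes, which were outside the comparison, stood above its level in the sham libraries. Mean FPKM in the infarct libraries was 2.72 for Ddx3y, 2.22 for Uty, 1.88 for Kdm5d and 4.57 for Eif2s3y, against 0.0869, 0.0618, 0.0498 and 0.169 in the sham libraries.

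Reads of the X-linked homologues assigned to the Y-linked genes are argued against, since the folds of Ddx3x, Kdm6a, Kdm5c and Eif2s3x lay between 0.844 and 0.967, while the smallest fold of a Y-linked gene was 27.1, for Eif2s3y at 10.6, 0.804 and 2.27 FPKM in infarct libraries 1 to 3, and 9.12 without infarct library 1. Loss of the Y chromosome from male cells in culture is argued against by Xist, whose lowest value was 63.1 FPKM. Female cells in all 6 libraries with some male cells in the infarct libraries remain a candidate explanation. Xist was lower in all 3 infarct libraries than in every sham library, at 59.9%, 77.7% and 85.3% of the sham mean in infarct libraries 1 to 3. The amounts did not match in order. The 4 Y-linked genes summed to 25.6, 2.36 and 6.21 FPKM in these libraries. Infarct library 2, the lowest of them in Y-linked genes, thus had less Xist than infarct library 3. Whether animals of both sexes were used or RNA was mixed later was not tested and stays open.

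Scaling or depth of the libraries is argued against for the lower endothelial genes, since 3699 other genes of like level had a median change of 0.0155 on the log2 scale against -1.65 for the list. A lower share of endothelial cells in the infarct cultures remains a candidate explanation. Within each group the list's members varied together, with a mean pairwise correlation of 0.356 after removal of group means, at percentile 100 of 10000 random lists matched on level, whose 95th percentile was 0.0759. Lower expression within the same cells cannot be told apart from it in bulk RNA. The log2 ratios of the separated members had an SD of 1.42, and the levels of these genes in each cell type were not measured here. The infarct itself therefore stays among the open explanations. So does a different source or sex mix of the cells, since the Y-linked genes were higher in every infarct than in every sham library. The most abundant separated members were Emcn and Cdh5, at 82.0 and 46.9 FPKM in sham libraries, and 3 of the 29 list members, Eng among them, are also in other lists.

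The 10 splits of 3 against 3 libraries are too few for a share under 0.05. The real split called 3 genes and the highest other split 5, and 3 of the 10 splits called as many. It passed 10 lists and the highest other split 19, with 8 of 10 splits as high. The absolute median of the endothelial list was 1.65 in the real split and 1.22 in the highest other, so 1 of 10 splits was as large.

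The genes called higher are short. Of 10 genes that exceeded 300 FPKM in a library and lay more than 50 times lower in another, 90% had no transcript of 300 nt or more. The share was 10.4% of all genes that exceeded 300 FPKM. Gm10060 and its copy Gm21769 are themselves among the 10. Value switching of very short gene models with near-identical copies is a candidate explanation for Gm10060, and no biological explanation was tested. Gm21769, which differs from it at 1 of 111 positions, was listed at 33097 FPKM in sham library 1 and at 0 in the other 5 libraries. Sham libraries 2 and 3 listed both at 0, which exchange within this pair does not account for, and no other copies were compared. Gm27390 stayed far below 300 FPKM and was not covered by the test of switching genes.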

How the results depend on the processing

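Fits without transcripts under 300 nt, on protein-coding genes only and with endothelial members left out of other lists were chosen after seeing the data. No paired analysis was possible because the infarct columns are numbered 1 to 3 and the infarct samples 2 to 4, which leaves their match ambiguous. The count of called genes was 3 (2 higher, 1 lower). It fell to 0 (0 and 0) without transcripts under 300 nt and on protein-coding genes, where limma gave 452 and 392 genes at an unadjusted p under 0.05. That count, 456 with all genes, was 1144 with library weights and 1012 of 25311 genes with no filter. Of these counts, only that with library weights exceeded the share of 0.05 that chance gives. The count of called genes was 1 (1 and 0) without a filter. With pseudocounts of 0.1 and 0.01 it was 2, none lower (0 in both). Without small, ribosomal and mitochondrial RNA, 1 was higher and the median of all genes shifted to -0.09. Leaving out 1 library gave 1 to 14 called genes, 1 to 2 higher and 0 to 12 lower, with 14 without sham library 1 and 1 without sham library 2, infarct library 1 or infarct library 2. The fits without short transcripts and on protein-coding genes leave out both genes called higher. Fits with 1 library left out also have fewer samples. The cause of the other shifts was not tested. The count of lists, 10, was 6 with a filter of 5 FPKM, 6 without the trend, 0 with an estimated correlation, 0 with fry and 10 to 16 with 1 library left out, the highest without infarct library 1. The endothelial list passed in 22 of 24 alternatives, all at the preset correlation of 0.01, with leave-one-out adjusted p from 6.33e-50 to 8.16e-25. Robust estimation, library weights, the other thresholds and lists without endothelial members could not alter its camera test, which gave 3.53e-38 in each. The list did not pass with an estimated correlation (0.315) or fry (0.160), which take the correlation between members from the data. The mean pairwise correlation of its members within groups was 0.356, so the p-values at the preset correlation overstate the evidence. The endothelial count over the list alone, 17, was 9 with a filter of 5 FPKM and 15 to 18 with 1 library left out. The S phase list reversed without sham library 3 (0.871) and infarct library 1 (0.116), in a leave-one-out range from 3.48e-10 to 0.871. The genes compared across alternatives kept their direction in all that could test them. Of them, 8 not called were past the threshold with 1 library left out. At an implied depth of 20.3 to 28.2 M fragments, very low values such as those of the Y-linked genes in sham libraries rest on few fragments.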

Other observations

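The imprinted-gene test in this part was chosen after the values were seen, as were the genes named.

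The values of C1qtnf6, Il33, Hgf and Spp1 were highest in infarct library 1. C1qtnf6 was at 217 FPKM there and at 13.1 to 14.9 in the other 5 libraries. Il33, an alarmin gene, was at 31.5 FPKM there, at 0.977 and 1.14 in infarct libraries 2 and 3 and at 1.41, 0.501 and 0.295 in sham libraries 1 to 3. Hgf, the gene of hepatocyte growth factor, was at 47.3 FPKM there, at 5.58 and 14.2 in infarct libraries 2 and 3 and at 10.2, 9.07 and 5.44 in sham libraries 1 to 3. Spp1, the gene of osteopontin, was at 552, 66.4 and 199 FPKM in infarct libraries 1 to 3 and at 42.2, 147 and 103 in sham libraries 1 to 3. The authors' deposited table calls all 4 higher, and none passed by limma.

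Mki67, a proliferation marker, was at 25.2, 49.2 and 15.1 FPKM in sham libraries 1 to 3 and at 43.6, 19.2 and 24.7 in infarct libraries 1 to 3. Col3a1, a collagen gene, was lowest in each group in the library where Mki67 was highest, at 1044, 440.4 and 1119 FPKM in sham and 552, 932 and 1099 in infarct libraries 1 to 3.

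Mest and Plagl1, which are imprinted genes, were at 10.8, 58.2 and 22.4 and at 4.01, 20.6 and 9.91 FPKM in sham libraries 1 to 3, and at 2.72, 0.294 and 0.465 and at 1.55, 3.37 and 1.70 in infarct libraries 1 to 3. A hypothesis that imprinted genes were lower together was tested on 23 genes. It was not borne out, since 10 of the 23 were lower and the median change was 0.04. An exact two-sided permutation test of the median over the splits of the libraries gave p = 0.6, and camera, which is not exact, gave p = 0.477. Without Mest and Plagl1 the exact permutation test gave p = 0.3 and camera p = 0.552.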
